A study of Mus musculus with 8 samples.

How the data were processed

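RNA from the red portion of the gastrocnemius, a calf muscle, was measured in 8 mice aged 14 to 16 weeks, 4 wild type and 4 homozygous for a mutant Pus1 gene. Per the labels, the strain was C57BL/6J after 5 generations of backcrossing, the 4 samples of each genotype were biological replicates, and 100 ng of RNA per sample was labelled with Cy3 or Cy5. Each array held 1 wild type and 1 mutant sample that carry the same individual number and sex in the labels. Arrays 1 and 2 held male pairs and arrays 3 and 4 female pairs. The wild type carried Cy3 on arrays 1 and 3 and Cy5 on arrays 2 and 4, so each sex was measured in both dye orientations. The 4 arrays shared 1 slide, so no slide batch could be tested.

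The deposited scanner files hold intensity, the raw median brightness of each spot and of its local background in each channel on a linear scale, per the file headers. Feature Extraction 10.7.3.1 made them, per the file headers and the submitters' processing notes. Processed intensity in the same files was background-subtracted, detrended and dye-normalized by that program, per the file headers. Their ratio is on the log10 scale, processed Cy5 over processed Cy3, per the file headers. Flags of 0 or 1 mark spots well above background, saturated spots and outliers, per the file headers. The authors' deposited value table is on the log2 scale, which was found from the values. The differences between its channels correlated with the scanner's own ratio, turned to log2, at r = 0.997, 0.991, 0.997 and 0.998 across probes on arrays 1 to 4, with slopes of 1.03, 1.04, 0.965 and 0.966, which also gave its direction. Each probe in it is centred on its median over the 8 samples, with a largest row median of 9.55e-07. Its column medians were -0.035, -0.062, 0.013 and 0.0036 for wild types 1 to 4 and -0.0016, 0.0066, 0.0045 and 0.019 for mutants 1 to 4. Scale, centring and direction are thus known from the values, and the steps that made the table are not given in the sources used here.

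The values were analysed in R 4.3.3 with limma 3.58.1. Median spot intensity was corrected with the local background median by normexp with an offset of 50. The design had named mean spot signals, which the files used here do not give, so median signals took their place, also in the alternative without background subtraction. Ratios were normalized by loess within each array, with control spots and outlier spots at weight 0, and turned to mutant over wild type. Each array has 62976 spots and 55681 probes other than controls. Probes were named by matching their accession, without version, to a RefSeq table of assembly GRCm38.p6, which was used for names, for neighbours and for membership of the window around Pus1. 27656 probes matched 1 gene name (20972 genes), 16194 lie in chromosome regions without a gene name and 11831 others had no match. Coordinates of regions are those of the scanner files, whose headers name build mm9.

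Probes were kept when at least 50% of their spots were well above background in all 4 samples of at least 1 genotype. This left 21152 probes, of which 14514 have a gene name and 6638 have none, and 6 of the probes had no value on some array because of outlier flags and were left out. The spots of a probe were averaged, and each gene was represented by its probe of highest mean brightness, which gave 11453 genes. The number of arrays limits the precision. The share of probes well above background was 45.0%, 47.3%, 39.7% and 42.4% in wild types 1 to 4 and 41.0%, 39.9%, 42.5% and 39.8% in mutants 1 to 4. A gene not well above background in any sample of a genotype has only a bound there. Its fold is given as "at least", from the mean of the brighter genotype against the mean, per sample, of the higher of the gene's own value and the lowest signal among probes well above background, per channel after loess and Aquantile.

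The genotype effect was fitted with lmFit and eBayes on log2 ratios, with a probe-specific dye term, on 2 residual degrees of freedom and a prior of 3.22. Tests were 2-sided, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. The array holds the pair, and the pairing comes from the shared array and the individual number in the labels. Deviations from the group means correlated within pairs 1 to 4 at r = 0.38, 0.25, 0.12 and 0.50 across genes, and a fit with no replicate block called 3 genes in place of 2. The difference between the sexes was tested as a genotype by sex term in the same model, with 1 residual degree of freedom. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Genes within 20 Mb of Pus1 were set against genes elsewhere by Fisher's exact test of the called genes and by the median absolute log2 change against 10000 random lists of equal size, matched on brightness in 10 bins.

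The comparisons, their tests, 34 gene lists, most of the alternatives and the rule for named genes were fixed before the data were examined. The rule names Pus1, then up to 12 genes in each direction that passed the threshold with the largest change and went the same way on 4 arrays, among genes with a symbol other than a Riken clone, Gm number, LOC or accession name. Where fewer pass, places up to 6 per direction go to the genes of smallest p, given as not passing. It also names, per list, up to 4 members past the threshold or else up to 2 of smallest p, then the 6 genes of largest difference between the sexes past the threshold, and up to 8 genes past the threshold near Pus1. A gene with only a bound is named only under those parts. Genes named outside the rule were chosen after their values were seen. They are Thap6, Rchy1, P2rx7, Mthfd2, Psph, Phgdh, Ddit4, Arntl, Per1, Tpm3, Tnnc1, Tnni1, Myl6b, Actc1, Fn1, Hba-a1, the beta globins, Fech, Abraxas1 and Zdhhc22. Some genes that the rule or a list would name are not reported here. Genes of the X and Y chromosomes served as a check of the sex labels.

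The steps were tested on simulated arrays drawn from normal distributions with the variances and dye effects of these arrays, genes independent of each other, with 200 changed genes of 11453 in 20 runs. The genotype fit recovered 72.2% of changes of 0.5, 98.7% of changes of 1 and 100% of changes of 2 on the log2 scale. The variances drawn were those after eBayes moderation, and 200 changed genes ease the adjusted threshold. Recovery with few changed genes can thus be lower, so these shares do not show that such changes are absent here. Of its calls 9.60% were false, and it made at most 2 calls where nothing was changed. The sex term recovered 2.84%, 59.0% and 98.9% of changes of these sizes and made up to 33 calls where nothing was changed. Camera found a list shifted by 0.3 in 20 of 20 runs at the preset correlation and in 0 of 20 runs with an estimated correlation, and it called up to 2 lists that were not shifted. The simulated genes were independent, so these runs do not speak for the preset correlation where members of a list move together. With an estimated correlation the test missed the shift in all runs, though no genes were correlated. Its failures thus do not argue against a shift of that size or smaller. The window test found a changed window in 20 of 20 runs and gave a p under 0.05 in 0 of 20 runs without one.

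The alternatives were no background subtraction, the scanner's own ratio, an offset of 16, median centring, Aquantile between arrays, no filter, a filter on all 8 samples, no dye term, the mean of a gene's probes, no replicate block, the array as a random effect (lmscFit, whose estimation reached its iteration limit for some genes), the authors' value table, each replicate left out, a variance trend with robust estimation, an adjusted p under 0.1, a fold of at least 1.5, a per-gene paired test without variance moderation, windows of 10 and 40 Mb, an estimated correlation and fry. Testing unnamed probes too, using the female pairs alone with no dye term and scaling between arrays were added after the data were seen. A dye term on the female arrays alone would leave no residual degrees of freedom. Mitochondrially encoded transcripts, 1 of the 34 lists, had 0 measured members and were not analysed here.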

Results

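Pus1 encodes pseudouridine synthase 1, an enzyme that converts uridine to pseudouridine in cytosolic and mitochondrial tRNAs. The series asked how its loss alters transcripts in red, slow skeletal muscle. Red gastrocnemius RNA of 4 wild type and 4 homozygous mutant mice was hybridised in 4 pairs on 2-colour arrays, 2 male pairs and 2 female pairs, with the dyes exchanged within each sex. Between 39.7% and 47.3% of probes were well above background per sample, and 11453 genes were tested. The Y-linked genes Ddx3y and Eif2s3y had mean log2 levels of 10.88 and 11.76 in the 4 males against 6.38 and 6.38 in the 4 females, and were well above background in the males alone. Xist, the X-inactivation transcript, was at 8.33 in females and 6.33 in males. All 8 samples matched their sex labels by these 3 genes, while Kdm5d was above background in 0 samples and 1 probe of Uty in 5 samples of both sexes.

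The Pus1 transcript fell in the mutants by 1.90 on the log2 scale (SE 0.10, n = 4 arrays), with ratios of -1.95, -1.53, -2.13 and -2.01 on arrays 1 to 4 (limma adjusted p = 0.0454). Mean log2 levels were 8.74 in wild type and 6.83 in mutant muscle. Its probe was well above background in 4 of 4 wild type and 0 of 4 mutant samples, so the transcript was at least 3.57-fold lower. The labels do not say which part of the gene is altered, and the array has 1 Pus1 probe. The change had the same direction under all alternatives that kept the gene, with adjusted p from 2.81e-31 to 0.868. It missed the threshold without replicate 1 (-1.95, adjusted p = 0.868), 2 (-2.02, 0.144), 3 (-1.86, 0.638) or 4 (-1.78, 0.250), and it measured -3.87 with the scanner's own ratio (adjusted p = 0.115).

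Apart from Pus1, 1 gene changed with genotype. Tesc, which encodes the calcium-binding protein tescalcin, rose 2.64-fold in the mutants, by 1.40 on the log2 scale (SE 0.08, n = 4 arrays, limma adjusted p = 0.0454), with array ratios of 1.51, 1.35, 1.65 and 1.09. Among genes with a symbol other than a clone or Gm number, the next 5 by p with higher values did not pass. They were Vsig10 at 0.70 ± 0.07 (SE), Ttc28 at 0.69 ± 0.07, Hsd17b11, a lipid droplet dehydrogenase, at 0.66 ± 0.08, Cox18, an inner membrane insertase needed for cytochrome c oxidase assembly, at 0.76 ± 0.11, and the stress-responsive transcription factor Atf5 at 0.53 ± 0.07. The 5 with lower values that did not pass were the peroxisomal membrane protein gene Pxmp2 at -1.08 ± 0.07, the DNA polymerase epsilon gene Pole at -0.78 ± 0.07, the galectin-3 gene Lgals3 at -0.73 ± 0.08, the keratin gene Krt18 at -0.67 ± 0.08 and Septin11 at -0.55 ± 0.07. Their adjusted p ran from 0.0653 for Pxmp2 to 0.546 for Cox18 and Atf5. Each of these 10 genes had 1 direction on 4 of 4 arrays, and Krt18 was above background in 3 of 4 mutants. Pxmp2 passed with no replicate block (adjusted p = 0.0125), with the array as a random effect, which did not converge for some genes, and with median centring, and its adjusted p ran from 1.75e-08 to 0.999 over the alternatives.

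At an unadjusted p under 0.05 there were 672 genes, 390 with higher and 282 with lower values in mutants, where chance gives 573. The median SE of a log2 change was 0.0807. The count of genes changed in Pus1 mutant muscle, 2 in all, ranged from 0 to 267 over the alternatives. It was 0 without replicate 1, 2, 3 or 4 each (limma, 302 to 1157 genes at an unadjusted p under 0.05), and 267 with median centring, 38 higher and 229 lower. Tesc did not pass without replicate 1 (1.44, adjusted p = 0.868), 2 (1.33, 0.404), 3 (1.36, 0.638) or 4 (1.47, 0.267), and its adjusted p over the alternatives ran from 3.72e-16 to 0.868.

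**Figure D1:**
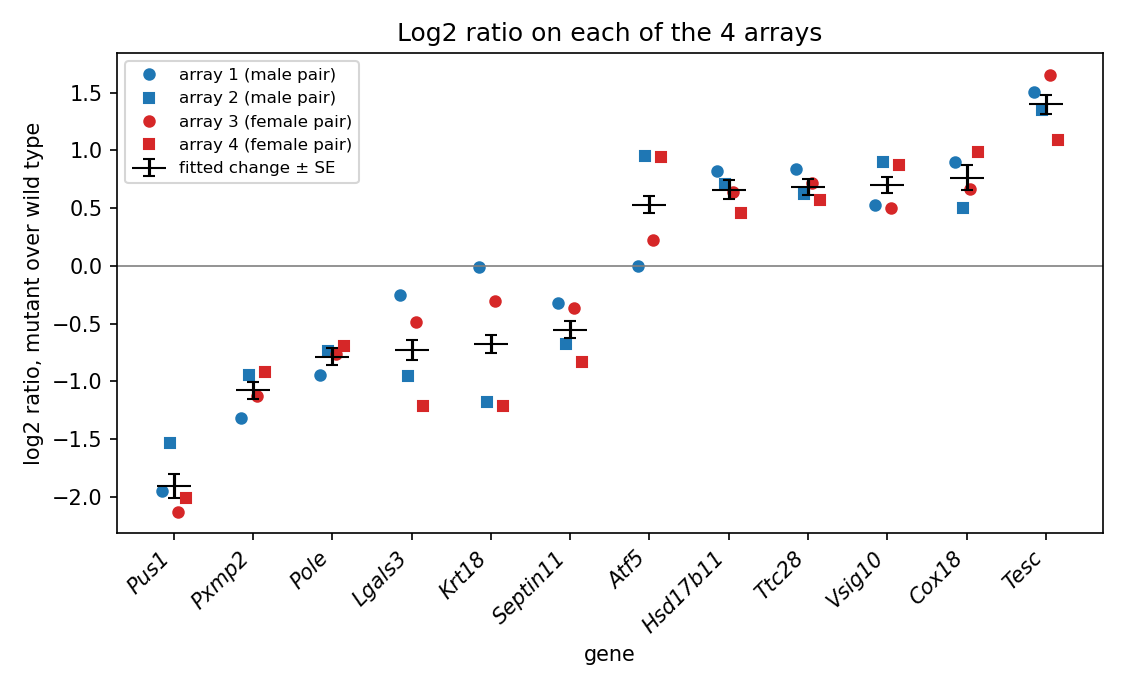
Log2 ratios of mutant over wild type on each of the 4 arrays (points, coloured by sex) for Pus1, Tesc and, in each direction, the 5 named genes of next smallest p, with the fitted change and its SE. Pus1 lies between -2.13 and -1.53 and Tesc between 1.09 and 1.65, while Atf5, Lgals3 and Krt18 differ more between arrays of opposite dye orientation.

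The labels name a backcross of 5 generations, so genes close to Pus1 on chromosome 5 were compared with those elsewhere. The 263 tested genes within 20 Mb of Pus1 differed more between the genotypes than other genes. Their median absolute log2 change was 0.109, against 0.0730 for the median random list and 0.0961 for the highest of 10000. These lists drew other genes of matched brightness and relabelled no arrays. They thus treat genes as independent and do not cover the spread between animals. With the ratios of array 3 turned in sign, the median in the window was 0.102. Adjusted over the window alone, 10 genes passed, 4 higher and 6 lower in mutants. The higher ones were Tesc, Vsig10, Ttc28 and Hsd17b11. The lower ones were Pxmp2 and Pole, among the tested genes closest to Pus1, Septin11, Thap6 at -0.45, the ubiquitin ligase gene Rchy1 at -0.46 and P2rx7, an ATP-gated channel gene, at -0.46 with 3 of 4 mutants above background. The limma adjusted p over the window ran from 0.00209 for Tesc to 0.0344 for P2rx7. At an unadjusted p under 0.05 lay 21.3% of genes in the window and 5.50% of the 11189 genes elsewhere. On chromosome 5, 37 of 694 genes (5.33%) had an unadjusted p under 0.01, and the next highest share was 1.92% on chromosome 19. Of the genes called by limma, Pus1 set aside, 1 lay in the window, Tesc, and 0 lay elsewhere (Fisher's exact test, 2-sided, p = 0.0230), against 25 and 104 genes at an unadjusted p under 0.01. With 1 call that p is no more than the window's share of the tested genes. For genes near Pus1 on chromosome 5, Fisher's exact p ran from 3.18e-14 with the array as a random effect (10 called in the window, 4 elsewhere), a fit that did not converge for some genes, to 1. It was 0.0576 with median centring (11 and 255), and 1 in female pairs alone with no dye term (0 and 6 by limma, 172 of all genes at an unadjusted p under 0.05) and without replicate 1, 2, 3 or 4, where limma called 0 genes (302 to 1157 at an unadjusted p under 0.05).

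Male and female effects correlated across the window's genes at Pearson r = 0.52 and Spearman rho = 0.47, against r = -0.0032 and rho = 0.027 across all genes, which are not independent replicates. Without the 445 genes called by the sex term, described below, r across the remaining genes was 0.14. Those genes were called for differing between the sexes, so leaving them out raises r in itself. The highest r among random lists was 0.233. These lists too drew genes and relabelled no arrays, so the spread between animals is not covered. Other tested probes of window genes gave 0.57 for Ttc28, -0.67 for Septin11 and 0.52 for Psph, in the direction of the probes used, while that of Abraxas1 (0.22 against -0.42) had the opposite sign.

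**Figure D2:**
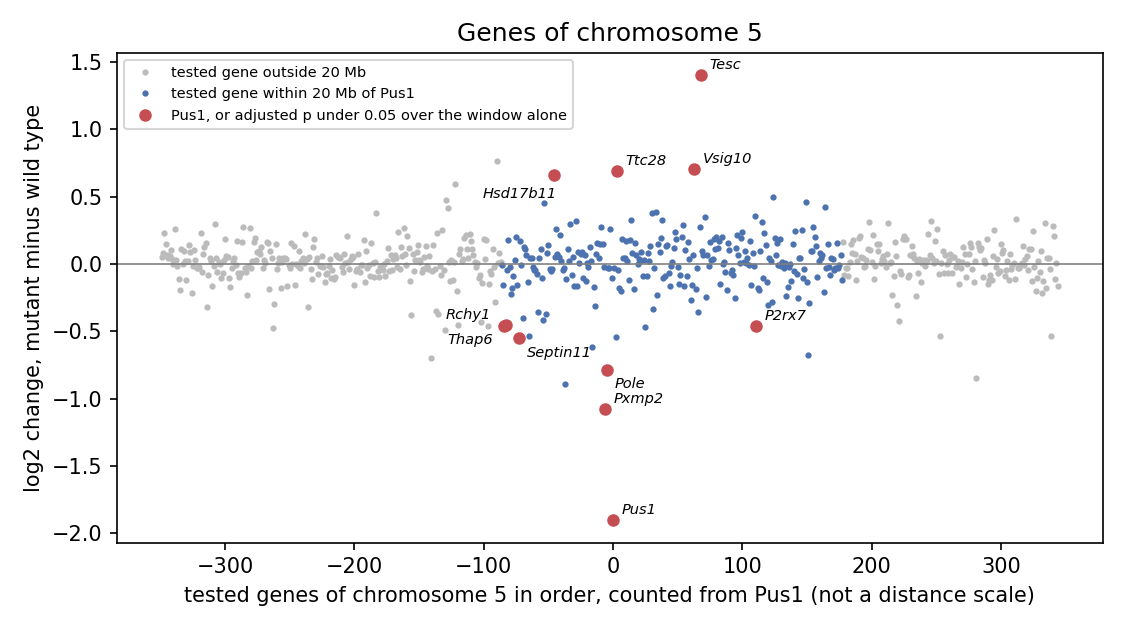
Log2 change, mutant minus wild type, of the tested genes of chromosome 5 in their order from Pus1 (not a distance scale), grey beyond 20 Mb and blue within. Red points are Pus1 at -1.90 and the 10 genes with adjusted p under 0.05 over the window alone, from Pxmp2 at -1.08 to Tesc at 1.40.

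Of the 33 gene lists with measured members, 7 shifted with genotype by camera at the preset correlation, 3 higher and 4 lower in mutants, and 0 did so with an estimated correlation, where each of the 7 had an adjusted p of 0.926. The estimates were 0.58 for the erythroid list, 0.56 for complexes II and III, 0.45 for slow fibre and 0.40 for complex I. They were 0.21 for extracellular matrix, 0.0068 for the integrated stress response and -0.061 for circadian genes, against the preset of 0.01. For the stress response and circadian lists the estimate lies below the preset. Their unadjusted camera p still rose from 0.00156 to 0.0831 and from 0.00389 to 0.0911, so the level of correlation is not why they failed. With an estimated correlation camera found 0 of 20 simulated shifts of 0.3, so its failures here do not argue against a list. By fry 1 list passed, that of circadian clock genes (adjusted p = 0.0452), and 0 passed its test for change in either direction. Of the fixed gene lists 4 passed with no replicate block and 3 without replicate 3. No listed gene passed over all genes tested in limma (0 genes, with 672 of all genes at an unadjusted p under 0.05). Of 66 named list members, 29 moved by over 1.5 times or turned sign with 1 replicate left out.

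Genes of the integrated stress response with serine and one-carbon metabolism rose as a list, with 17 of 21 measured members higher and a median log2 change of 0.10 (camera adjusted p = 0.0176, and adjusted p = 0.926 with an estimated correlation). The list medians on arrays 1 to 4 were 0.15, 0.11, 0.093 and 0.10. Adjusted over the list alone, 4 genes rose, each higher on 4 of 4 arrays. These were Atf5 (0.53 ± 0.07 SE), the asparagine synthetase gene Asns (0.35 ± 0.07), the mitochondrial folate enzyme gene Mthfd2 (0.50 ± 0.11) and the serine synthesis gene Psph (0.42 ± 0.09), which lies in the window around Pus1. Phgdh, the first enzyme of serine synthesis, went the other way at -0.66 and Ddit4 at -0.58, neither passing, and both differed between the sexes, with male effects of -1.14 and -1.05 and female effects of -0.18 and -0.10 (limma adjusted p of the sex term 0.0110 and 0.0413). Both are among 420 genes, described below, with median effects of -1.09 in males and 0.10 in females. Most of that difference was extra signal in both male wild types, so a response of these genes in males cannot be told apart from it. The shift did not pass without replicate 4 (median 0.066, adjusted p = 0.157), with the scanner's own ratio (0.0637) or with median centring (0.0594). Without replicate 1 the median was 0.052 (adjusted p = 0.0230), and its adjusted p over the alternatives ran from 0.00521 to 0.157, the estimated correlation aside.

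Subunits of the respiratory chain had small negative shifts. Nuclear-encoded complex I genes were lower in 29 of 37 members (median -0.049) and those of complexes II and III in 12 of 14 (median -0.074), each with camera adjusted p = 0.0327 and adjusted p = 0.926 with an estimated correlation. The members of smallest p were Ndufb5 at -0.17 and Ndufb10 at -0.15, and Sdhb, of succinate dehydrogenase, at -0.17 and the cytochrome c gene Cycs at -0.13. Adjusted over the list alone 0 genes passed in either list. The list medians on arrays 1 to 4 were 0.067, -0.25, 0.037 and -0.065 for complex I and -0.011, -0.31, 0.095 and -0.10 for complexes II and III. Complex I did not pass without replicate 2 (median -0.011, adjusted p = 0.735), without replicate 3 (-0.041, 0.243) or with no replicate block (0.0527), within 0.00512 to 0.735 over the alternatives, the estimated correlation aside. Complexes II and III did not pass without replicate 1 (-0.072, adjusted p = 0.175), 2 (-0.020, 0.735) or 3 (-0.080, 0.0792), within 0.00528 to 0.850, and in the authors' value table the 2 medians turned to 0.021 and 0.012. Without replicate 4 the medians were -0.098 and -0.13. By camera both lists also missed the threshold with no dye term (adjusted p = 0.0940 each), with no filter (0.0748 each) and with median centring (0.586 and 0.409). Complex IV (median -0.017, adjusted p = 0.680, with Cox7a2 at -0.11 and Cox6a1 at -0.15) and ATP synthase (median -0.033, adjusted p = 0.187, with Atp5g3 at -0.13 and Atp5l at -0.091) did not pass.

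The machinery of mitochondrial translation did not shift by camera. Mitochondrial ribosomal proteins had 31 members higher and 46 lower of 77 (median -0.023, adjusted p = 0.151), with Mrpl51 and Mrpl12 at -0.15 each. Mitochondrial tRNA modification and processing genes had 13 of 18 members higher (median 0.058, adjusted p = 0.157), with Trmt5 at 0.17 and Qtrt1 at 0.19. Mitochondrial aminoacyl-tRNA synthetases had a median of 0.011 (20 measured, adjusted p = 0.737), with Wars2 at -0.33 and Gars at 0.14. The other pseudouridine synthases were 6 higher and 5 lower of 11 (median 0.018, adjusted p = 0.871), with Trub1 at 0.20 and Pus7 at -0.10. Mitochondrial biogenesis and dynamics genes (21 measured, median -0.016, adjusted p = 0.680, with Mfn2 at -0.13 and Twnk at -0.15) and mitochondrial chaperones and proteases (15 measured, median -0.011, adjusted p = 0.737, with Dnaja3 at -0.15 and Phb at -0.16) did not pass either. Adjusted over the list alone, 0 genes passed in each of these 6 lists. Cytosolic ribosomal proteins had 41 of 56 members higher (median 0.036, adjusted p = 0.151, 0 genes adjusted over the list alone), with Rpl10a at 0.25 and Rps27 at 0.13.

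Fuel pathways did not pass. Glycolysis genes had a median of -0.035 (20 measured, adjusted p = 0.292), with Pgm1 at 0.22 and the lactate dehydrogenase gene Ldha at -0.18. The tricarboxylic acid cycle list had 15 of 20 members lower (median -0.024, adjusted p = 0.187), with Idh3a at -0.21 and Ogdh at -0.10. Fatty acid oxidation genes had a median of 0.0012, a mean of -0.0069 and a downward test (31 measured, adjusted p = 0.892), with the lipid droplet gene Plin5 at -0.22 and Hadhb at 0.16. Antioxidant genes had a median of 0.050 (19 measured, adjusted p = 0.737), with Gpx3 at 0.44 and the catalase gene Cat at -0.62. Cat differed between the sexes, with a male effect of -1.21 and a female effect of -0.030 (limma adjusted p of the sex term 0.00582), and its change ran from -0.95 to -0.29 with 1 replicate left out. It too is among the 420 genes, described below, whose difference was mostly extra signal in both male wild types. Adjusted over the list alone, 0 genes passed in each of these 4 lists.

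Slow-twitch fibre genes rose as a list, with 10 of 14 members higher and a median of 0.21 (camera adjusted p = 0.0332, and adjusted p = 0.926 with an estimated correlation). The slow troponin T gene Tnnt1 was at 0.42 ± 0.09 (SE), Tpm3 at 0.60, Tnnc1 at 0.39 and Tnni1 at 0.34, while Fhl2 was at -0.35 ± 0.08, and 0 genes passed adjusted over the list alone. The list medians on arrays 1 to 4 were 0.18, -0.12, 0.40 and 0.33. The median was 0.36 in female pairs and 0.045 in male pairs, and without replicate 3 or replicate 4 it was 0.11 (adjusted p = 0.441 and 0.188), against 0.33 without replicate 2. It also missed the threshold with no replicate block (adjusted p = 0.120), and over the alternatives its adjusted p ran from 3.56e-08 to 0.441, the estimated correlation aside. Fast-twitch fibre genes were higher in 12 of 15 members (median 0.094, adjusted p = 0.292, 0 genes adjusted over the list alone), with the myosin gene Myh2 at -0.20 and Mylk2 at 0.14. Atrophy and denervation genes had a median of 0.022, a mean of -0.0036 and an upward test (16 measured, adjusted p = 0.733, 0 genes adjusted over the list alone), with the ubiquitin ligase gene Trim63 at 0.24 and the acetylcholine receptor gene Chrnd at 0.14. The regeneration list did not pass (12 measured, median -0.029, mean -0.19, adjusted p = 0.178), and 2 of its genes passed with lower fitted values adjusted over the list alone. These were Csrp3, the muscle LIM protein gene, at -0.81 ± 0.11 (SE), lower on 4 of 4 arrays, and the embryonic myosin gene Myh3 at -1.08 ± 0.19, with array ratios of 0.58, -1.95, 0.046 and -2.99. For Myh3 the dye term takes up the gap between arrays 1 and 3 and arrays 2 and 4, which the SE leaves out.

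Circadian clock genes fell as a list, with 10 of 15 members lower and a median of -0.13 (camera adjusted p = 0.0321, and adjusted p = 0.926 with an estimated correlation). The list medians on arrays 1 to 4 were -0.10, -0.14, -0.22 and -0.030. Ciart, a repressor of the clock, fell by 0.44 adjusted over the list alone (1 gene), lower on 4 of 4 arrays. Cry2 was at -0.25, Per1 at -0.48 and Arntl, which encodes the clock activator BMAL1, at 0.46, each with 1 direction on 4 of 4 arrays and none passing. The median was -0.11 without replicate 3 (adjusted p = 0.0542) and -0.22 without replicate 4 (adjusted p = 0.148), and with no replicate block the adjusted p was 0.0527, within 0.0133 to 0.192 over the alternatives, the estimated correlation aside. By camera the clock list also missed the threshold with no dye term (adjusted p = 0.0940), with no filter (0.0932) and with median centring (0.192). Immediate early genes did not pass (12 measured, median 0.056, adjusted p = 0.761), with Nr4a1 at -0.33 and Egr1 at 1.02 ± 0.49 (SE), where array 1 alone gave 3.08. Heat shock genes were 6 higher and 6 lower of 12 (median -0.0019, adjusted p = 0.737), with Hspb7 at -0.24 and Hspa1a at -0.56, where array 2 gave -1.65 and the other arrays -0.38 to 0.019. In these last 2 lists 0 genes passed adjusted over the list alone.

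Extracellular matrix and fibroblast genes fell as a list, with 11 of 16 members lower and a median of -0.14 (camera adjusted p = 0.0176, and adjusted p = 0.926 with an estimated correlation). Adjusted over the list alone, 2 genes passed with lower fitted values, the collagen gene Col3a1 at -0.57 ± 0.11 (SE) and the periostin gene Postn at -0.77 ± 0.16, and Fn1, the fibronectin gene, was at -0.35 without passing. The dye term takes up any gap between arrays 1 and 3 and arrays 2 and 4, so these SEs leave such a gap out. The list medians were -0.014, -0.63, 0.49 and -0.58 on arrays 1 to 4. Without replicate 1 the median was -0.042 (adjusted p = 0.655), without replicate 2 -0.088 and without replicate 3 -0.26, and with no dye term the adjusted p was 0.0940. In female pairs alone, also with no dye term, the test turned upward with a median of -0.012 (adjusted p = 0.763). The adjusted p over the alternatives ran from 3.31e-06 to 0.763, the estimated correlation aside.

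Markers of other cell types in muscle were mostly without a shift. Adipocyte genes had a median of -0.039 with a mean of 0.15 and an upward test (8 measured, adjusted p = 0.737), and 2 passed with higher fitted values adjusted over the list alone, the stearoyl-CoA desaturase gene Scd1 at 0.59 ± 0.09 (SE) and the adipsin gene Cfd at 0.80 ± 0.18. Scd1 was higher on 2 of 4 arrays, with ratios of -0.53, 1.44, -0.30 and 1.76 on arrays 1 to 4, and Cfd on 3 of 4, with 0.14, 1.59, -0.73 and 2.23. The dye term takes up the gap between arrays 1 and 3 and arrays 2 and 4, so these SEs leave that gap out. Macrophage markers (10 measured, median -0.032, adjusted p = 0.737) included Itgam, with a male effect of -1.33 and a female effect of 0.13 (-0.60 over both), and Mrc1 at 0.16. Lymphocyte markers (3 measured, median -0.0077, mean 0.037, upward test, adjusted p = 0.737) included Cd4 at -0.20 and the B cell receptor gene Cd79b, which rose by 0.32 adjusted over the list alone (1 gene). Endothelial markers (11 measured, median -0.0087, mean 8.66e-05, downward test, adjusted p = 0.737) included Flt1 at -0.20 and Egfl7 at 0.079. Smooth muscle and pericyte markers (9 measured, median 0.15, adjusted p = 0.245) included Cnn1 at 0.40 and Rgs5 at -0.19. Schwann cell and nerve markers (8 measured, median 0.16, adjusted p = 0.245) included S100b at 0.25, with -0.61 on array 3 and 0.21 to 0.87 on the other arrays. Interferon-stimulated genes (11 measured, median -0.047, mean 0.046, upward test, adjusted p = 0.737) included Rsad2 at 0.51, with 1.24 on array 4 and 0.094 to 0.42 on the other arrays, and Usp18 at 0.20. In the macrophage, endothelial, smooth muscle, nerve and interferon lists 0 genes passed adjusted over the list alone.

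**Figure D3:**
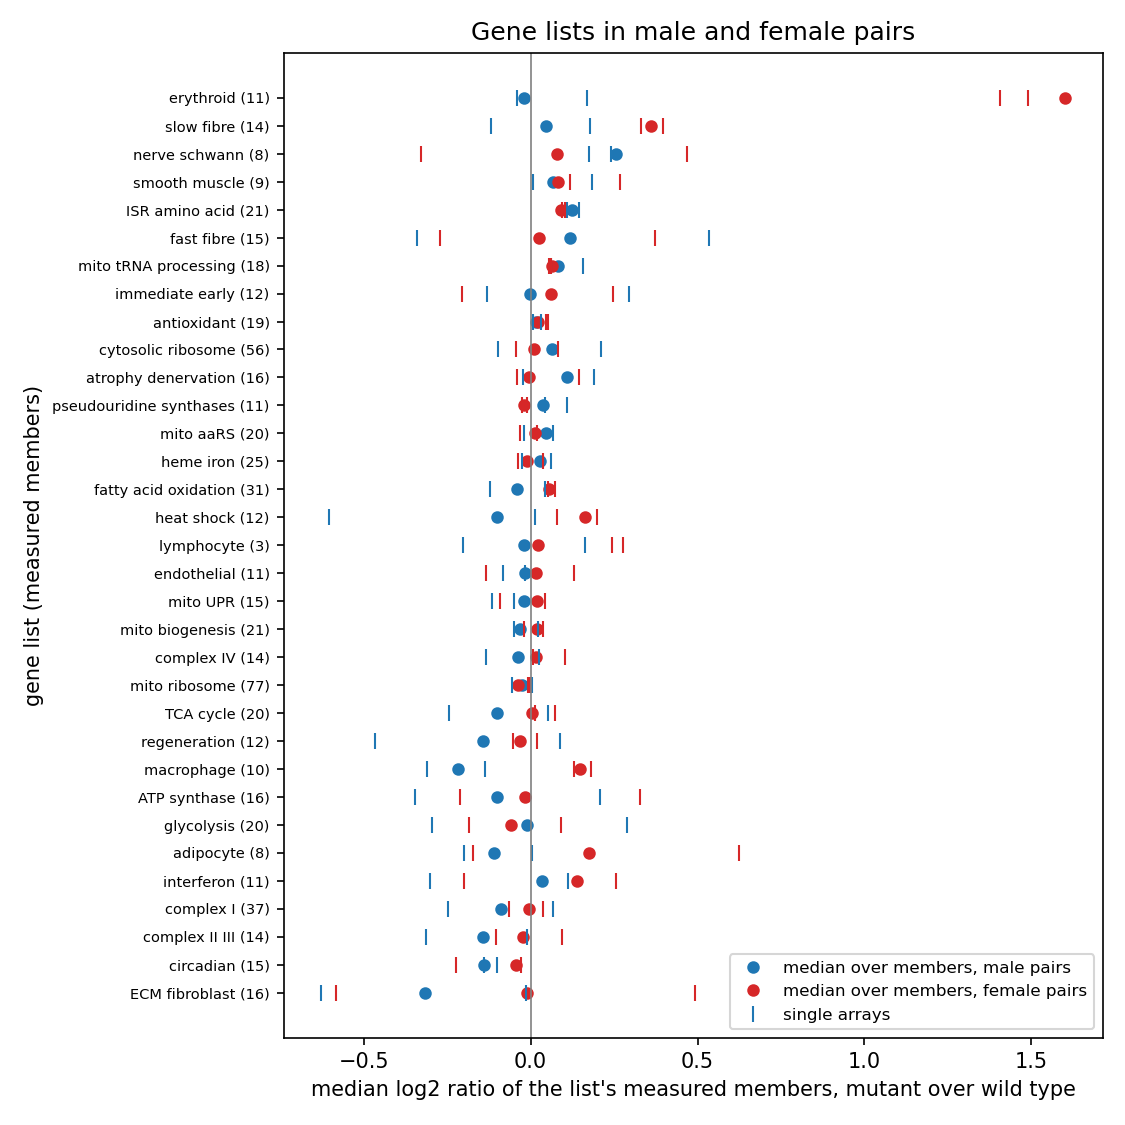
Median log2 ratio, mutant over wild type, of the measured members of each of 33 gene lists in male and female pairs (points) and on single arrays (ticks). The erythroid list stands at 1.60 in female and -0.021 in male pairs, and the integrated stress response list at 0.092 and 0.12.

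Erythroid genes were higher in the mutants of the female pairs. The list of 11 measured members rose with a median of 0.76 (camera adjusted p = 0.0176, and adjusted p = 0.926 with an estimated correlation), with array medians of -0.042, 0.17, 1.41 and 1.49. Hba-a2, an alpha globin gene, was at 0.96 ± 0.34 (SE) and Alas2, which starts heme synthesis in red cells, at 0.89 ± 0.32, with 0 genes passing adjusted over the list alone. Mean log2 levels of Hba-a2 were 17.76 in mutants and 16.80 in wild types. In the genotype by sex term 7 of the 11 passed, among them genes with female effects of 1.61 to 1.82 for the globins Hba-a1, Hbb-b1, Hbb-b2 and Hbb-bt, 1.68 for Hba-a2 and 1.60 for Alas2, and male effects of -0.24 to 0.25. Fech, also in the heme list, was at 0.0085. Without replicate 3 the list median was 0.27 (adjusted p = 0.203) and without replicate 4 it was 0.37 (adjusted p = 0.215), against 1.29 without replicate 1, within adjusted p of 5.41e-38 to 0.215 over the alternatives, the estimated correlation aside. Heme synthesis and iron handling genes did not shift (25 measured, median 0.0085, adjusted p = 0.737, 0 genes adjusted over the list alone), with the mitochondrial iron importer gene Slc25a37 at 0.53 and the transferrin receptor gene Tfrc at -0.29.

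The effect of genotype differed between the sexes for 445 genes by the sex term, 420 with a higher and 25 with a lower effect in females. Simulations of the same fit without change gave up to 33 calls. Their genes were independent, so they cannot hold a signal shared by many genes of 1 sample and are no benchmark for this count. The 6 with the largest difference were Slfn9 (3.29 ± 0.16 SE), the MHC class I gene H2-Q4 (3.27 ± 0.15), Fbxl12os (2.89 ± 0.18), the nuclear receptor gene Nr1i3 (2.51 ± 0.27), Iqcf4 (2.48 ± 0.18) and Zfp488 (2.45 ± 0.15), with limma adjusted p from 0.000857 to 0.00301. Their male effects ran from -3.30 to -2.22 and their female effects from -0.19 to 0.23. Over the 420 genes the median male effect was -1.09 and the median female effect 0.10, and 398 were higher in wild type on both male arrays. Their median log2 level was 11.32 and 11.88 in the 2 male wild types, 10.56 and 10.23 in the male mutants, and between 10.46 and 10.79 in the 4 female samples. The sex difference in the genotype effect called 0 genes with the scanner's own ratio (1774 at an unadjusted p under 0.05) and 0 with no dye term (502), and 125 with no replicate block.

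By camera 5 lists differed between the sexes. The erythroid (adjusted p = 1.31e-08), macrophage (0.000254), heat shock (0.00494), slow fibre (0.0139) and extracellular matrix lists (0.0484) had higher effects in females, and 0 lists passed with an estimated correlation (adjusted p = 0.958). The preset counts the related globin genes of the erythroid list as nearly separate members. The size of that p thus does not measure the spread between animals. Power with an estimated correlation was not simulated for the sex term. Male and female medians were -0.22 and 0.15 for macrophage markers, -0.10 and 0.16 for heat shock genes and -0.32 and -0.012 for matrix genes. Among single members, the integrin gene Itgam differed by 1.46 and the cardiac actin gene Actc1 by 1.73, higher in females, and the myosin light chain gene Myl6b by -1.02. In female pairs alone, fitted with no dye term, 7 genes passed, Pus1 lower and Zdhhc22, Hba-a1, Hbb-b1, Hbb-b2, Hbb-bt and Alas2 higher.

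Probes for chromosome regions without a gene name were well above background in 27.0% and 31.3% of cases in male wild types 1 and 2, 22.3% and 20.5% in male mutants 1 and 2, 19.6% and 23.4% in female wild types 3 and 4, and 23.5% and 19.7% in female mutants 3 and 4. Among 70 regions with at least 5 tested probes, 1 on chromosome 16 (23992037 to 24001037, forward strand, mm9) had 6 of 7 probes higher in mutants with a median log2 change of 1.11. Its medians on arrays 1 to 4 were 1.03, 0.67, 1.54 and 0.73. Another on chromosome 6 (83541250 to 83560425, forward strand, mm9) had 5 of 5 probes higher with a median of 0.80 and array medians of 0.68, 0.99, 0.96 and 0.62. With the 6637 unnamed probes tested too, limma called 0 of 18090 features (990 at an unadjusted p under 0.05, smallest adjusted p 0.128).

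**Figure D4:**
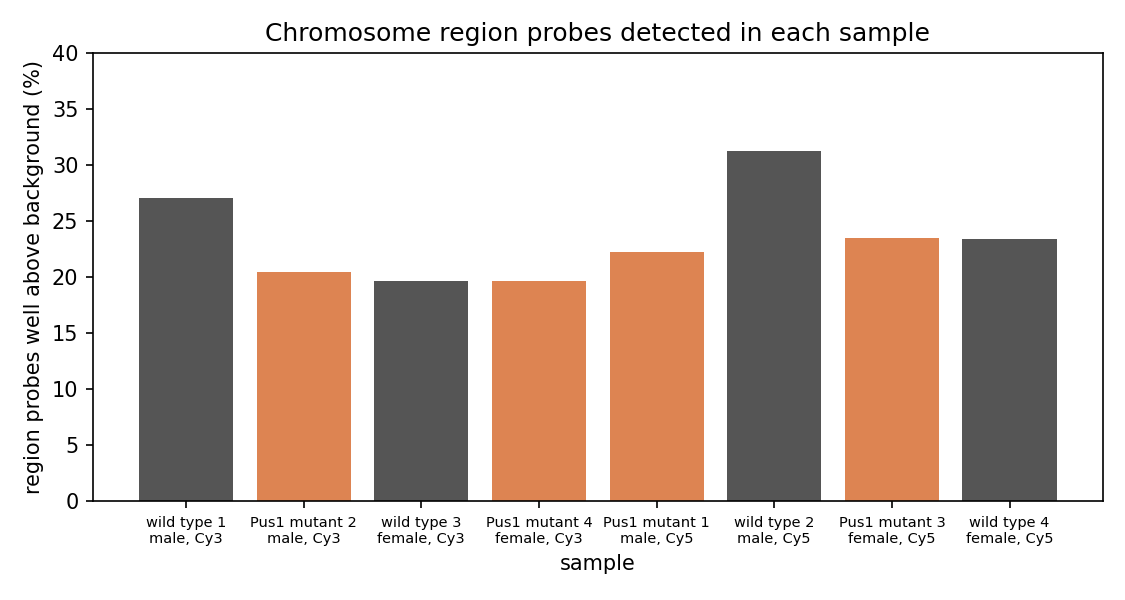
Share of chromosome region probes well above background in each of the 8 samples, in percent, Cy3 samples first and then Cy5, coloured by genotype. Male wild types stand at 27.0% and 31.3%, and the other 6 samples between 19.6% and 23.5%.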

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

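All tests of an explanation in this part were chosen after the result was seen.

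The effect of genotype differed between females and males for 445 genes, with Slfn9 (3.29), H2-Q4 (3.27), Fbxl12os (2.89), Nr1i3 (2.51), Iqcf4 (2.48) and Zfp488 (2.45) furthest apart on the log2 scale, and most of the difference was extra signal in both male wild type samples. In 89 of the 420 genes, 112 other probes, all dimmer than the probe in the pattern, had a median difference of 0.080 and an upper quartile of 0.34, below the lower quartile of 1.05 of the probes in the pattern. The probes in the pattern were picked for a large difference and each is its gene's brightest, so part of the gap was set by selection. The background offset also draws ratios of dim probes toward 0: Pus1 was at -1.90 here and at -2.32 with an offset of 16. As all the other probes were dimmer, their median of 0.080 cannot decide on a change of whole transcripts. Such a change stays open for these genes. Genomic DNA or another signal added to all probes alike stays open here. Loess within each array takes out shifts that go with brightness, so dimmer probes need not show it. Signal specific to single probes, with that median of 0.080 against 1.31, may account for it in those genes. In the other 331 genes an added signal and a difference between the sexes, untested there, stay open: the extra intensity of region probes had medians of 6.83 and 7.67 in male wild types 1 and 2, with an upper quartile of up to 28.5, against medians of 174.5 and 622.8 and lower quartiles of 40.7 and -97.8 for probes in the pattern.

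By camera the sex term also set apart the erythroid (adjusted p = 1.31e-08), macrophage (0.000254), heat shock (0.00494), slow fibre (0.0139) and extracellular matrix (0.0484) lists, none of which passed with an estimated correlation (adjusted p = 0.958). For the erythroid list, the excess signal of the male wild types is argued against by a median male effect of -0.021, where that excess gives negative values. More red blood cell RNA in the female mutant samples stays open: the 6 globin and Alas2 probes that make up most of the pattern were higher by 1.10 to 2.25, and of the 5 other erythroid genes 2 were higher in mutants on both female arrays. Among these 5, Fech is also in the heme list. Whether blood left in the tissue, the genotype or the sex is behind the difference was not tested with 2 female pairs.

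Of 120 groups of 4 arrays or samples, 3 had 1 value far from the rest, where chance gives about 1 in 20. These were Rpl10a on array 2, with a log2 ratio of 0.50, the median of the mitochondrial tRNA processing list on array 1, 0.16, and that of the fatty acid oxidation list on array 2, -0.12. Probes without a gene name lie outside the gene-level comparisons, and 2 regions stood out there, with median log2 changes of 1.11 on chromosome 16 and 0.80 on chromosome 6.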

How the results depend on the processing

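Unnamed probes, female pairs alone with no dye term and scaling between arrays were tried only after the results were seen. The setting of female pairs thus drops both the male arrays and the dye term. Signal over background limits the values, as Pus1 itself is below it in mutants and has no value with a filter on all 8 samples. The sex term could not be tested with a replicate left out, which leaves no residual degrees of freedom, and was not run with the array as a random effect or the authors' value table.

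Against 2 in the chosen settings, the number of genes changed in Pus1 mutant muscle was 0 with the scanner's own ratio (limma, 783 at an unadjusted p under 0.05), an offset of 16 (716), a filter on all 8 samples (628), the authors' value table (724), unnamed probes (990) and scaling (727), 0 to 0 without 1 replicate (302 to 1157), 0 by a per-gene paired test without variance moderation, 1 with no dye term, 7 in female pairs with no dye term, 15 with the array as a random effect (7 higher, 8 lower), where the fit reached its iteration limit for some genes, and 267 with median centring (38 higher, 229 lower), where eBayes gave all genes 1 common variance. With no replicate block it was 3, as Pxmp2 also passed, and the complex I, slow fibre and circadian lists did not. In the comparison of the genotypes it changed no other call of a named gene or list. The Pus1 transcript missed the threshold at -3.87 with the scanner's own ratio, -2.32 with an offset of 16, -3.83 in the value table, -1.93 with scaling and -2.02 to -1.78 without 1 replicate. Of the fixed gene lists 4 passed with the scanner's own ratio, median centring, no filter and no replicate block each, 3 with no dye term (3 higher, 0 lower), 3 to 9 without 1 replicate, 0 with an estimated correlation and 1 by fry, against 7. The sex difference in the genotype effect was called for 0 genes with the scanner's own ratio (1774 at an unadjusted p under 0.05) and with no dye term (502), and for 125 with no replicate block, against 445. Genes near Pus1 on chromosome 5 kept a median absolute change of 0.0957 to 0.156 and a random-list p of at most 0.0031 under all alternatives. Signs turned for Cox7a2 (0.0014) and Ogdh (0.0027) in the value table, where the medians of the complex I (0.021) and complexes II and III (0.012) lists also turned while their tests stayed downward, and in female pairs for Cox6a1 (0.053), Itgam (0.13), Cd4 (0.023), H2-Q4 (0.13), Fbxl12os (0.071), Iqcf4 (0.060), Zfp488 (0.23) and the test of the matrix list (median -0.012). Apart from the replicates left out, which lower the residual degrees of freedom, and the filter, which removes Pus1, the cause was not tested. Among single genes and single lists, 1580 values kept their direction and side of the threshold, 52 lost a call, 40 gained one and 10 turned, lists by the direction of their test. Most of the 1580 are genes without a call in the chosen settings, which had none to lose. Only Tesc and the 7 lists that passed had one, with Pus1 counted apart. Tesc lost its call in 12 alternatives and kept it in 7. Complex I and complexes II and III each lost it in 9 and kept it in 9, and the other lists lost it in 2 to 7.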

Other observations

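The tests of explanations for genes near Pus1 were chosen only after the result was seen; the comparisons with other splits were set beforehand.

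Several gene groups had array medians that differed with the dye orientation, which was not tested for lists. Fast-twitch fibre genes had medians of 0.54 and 0.37 on arrays 1 and 3, where the mutant carried Cy5, and -0.34 and -0.27 on arrays 2 and 4. ATP synthase subunits gave 0.21 and 0.33 against -0.35 and -0.21. Among lists that passed the test of genotype, extracellular matrix genes gave -0.014 and 0.49 against -0.63 and -0.58, complex I 0.067 and 0.037 against -0.25 and -0.065, and complexes II and III -0.011 and 0.095 against -0.31 and -0.10. For single genes, the embryonic myosin gene Myh3 gave 0.58 and 0.046 against -1.95 and -2.99. Across genes, which are not independent replicates, array ratios correlated at r = 0.30 between the 2 male arrays and -0.33 between the 2 female arrays, 0.14 between arrays 1 and 3 and 0.43 between arrays 2 and 4. All 4 arrays had 1 direction for 1195 genes (10.4%), where chance gives 12.5%. The dye term itself called 0 genes in limma, with 2402 at an unadjusted p under 0.05.

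A region without a gene name on chromosome 5 (137392195 to 137426421, forward strand, mm9) had 5 of 5 probes higher in mutants with a median log2 change of 0.47. The reverse strand of the chromosome 16 region had 4 of 5 probes higher, with a median of 0.47.

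An unadjusted p under 0.05 was more frequent among genes near Pus1 than among genes further along the same chromosome, with no significance test of the difference in shares. At an unadjusted p under 0.05 lay 21.3% within 20 Mb and 8.29% of the 217 genes beyond 40 Mb, in line with a chromosome segment around Pus1 that differs between the genotypes, which may date from the strain that carried the mutation. Sequence differences under single probes stay open as a contribution: for 9 of 24 genes with another tested probe, 7 of the 9 went the same way, with a median of 0.47 in that direction and quartiles of 0.10 to 0.52 against 0.42 for the probes used. An effect of Pus1 loss on these genes was not tested.

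Turning the signs of arrays gives 7 groupings, the real one included, too few for a share under 0.05. The grouping equal to the dye orientation is left out, as it cannot be fitted beside the dye term. For genes the real value was 2 and the highest other 0 (limma, 143 to 1195 at an unadjusted p under 0.05), and for the median absolute change near Pus1 0.109 against 0.102, with 1 of 7 groupings as high in each. For lists it was 7 against 11, with 5 of 7 as high. Without pairing of arrays, and with the split by dye left out too, 2 of 34 splits of the samples called as many genes as the real 3, a share above 0.05. The other of these, with 555, is the highest and parts males from females, a labelled difference and a structure of the samples, so this share does not settle whether chance can be excluded.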
